A study of Mus musculus with 8 samples.

How the data were processed

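RNA sequencing libraries were made from sorted tdTomato-positive, live cells of mouse duodenal organoids after 24 h of doxycycline at 2 µg/ml. Each library started from 100 ng of total RNA, prepared with ScriptSeq and read as pairs of 50 bp. The 8 libraries fell into 4 groups of 2: LUC, PIK3CA, CTNNB1 and CTNNB1_PIK3CA, assigned from the sample titles. The deposited signal values, 1 per gene and library, are gene counts that the authors had divided by 1 size factor per library. Per the submitters' processing notes the reads were aligned with STAR to GRCm38, counted with HTSeq and normalized with DESeq; versions were not stated, and the annotation release and the use of read strand were not given in the sources used here.

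Every nonzero value was a whole multiple of its library's smallest nonzero value, for 100% of values within a tolerance of 0.01 reads, so whole reads were recovered by dividing by that step. Size factors recomputed from the recovered reads by the median-of-ratios rule divided by the implied ones gave ratios between 0.9999 and 1.0001. A library had reads in 20283 to 21292 genes. For genes with at least 20 reads, the chi-square statistic of replicate reads per degree of freedom was between 22.0 and 68.3, so the spread between libraries was far above counting error. Intervals and floors cover counting error only. Of the 47289 gene symbols, 94.9% were in the reference annotation, which gave identifiers, coordinates and biotypes; chromosome positions are on GRCm38.

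The plan had named edgeR for a file of counts and limma for a file of normalized values, which this deposit is. Genes were tested with limma 3.58.1 (R 4.3.3, statmod 1.5.0) on log2 of the value plus a pseudocount of 1. A gene was tested where at least 2 libraries had a value of at least 10, which left 15581 genes. The fit had 1 mean per group over all 8 libraries, an intensity trend and robust empirical Bayes moderation, with 4 residual degrees of freedom and a prior of 7.83. Comparisons were CTNNB1, PIK3CA and CTNNB1_PIK3CA against LUC, CTNNB1_PIK3CA against each single transgene, and the interaction, which is the change in CTNNB1_PIK3CA minus the sum of the single changes. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Errors are SDs of a group's 2 libraries, limma SEs or, for flagged results, SEs over genes, which are not independent. Labels share no replicate numbers, so no test was paired.

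The 28 gene lists were written from textbook knowledge, and tested with camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Counts adjusted over the list alone used the members' p-values only. The lists were Wnt/beta-catenin targets, Lgr5 crypt base stem cell, Paneth, goblet, enteroendocrine, tuft and enterocyte markers, replication and mitotic genes, FoxO targets, sterol synthesis, glycolysis, ATF4 targets, ribosome biogenesis, MAPK output, YAP and fetal epithelium, Notch, adhesion, p53 targets, stress immediate early genes, unfolded protein response, interferon response, stromal, immune and endothelial markers, mitochondrially encoded genes, sex-linked genes and duodenal against ileal identity. Olfm4, Nupr1 and others are in more than 1 list.

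Genes were named by a rule: in each comparison the transgenes' own genes, the 10 largest rises and 10 largest falls past the threshold with a mean value of at least 10 and both libraries of a group above both of the other, without predicted models and unnamed genes, and up to 4 members of each list with the smallest adjusted p. For the interaction the separation of libraries was not required. Predicted gene models, pseudogenes, and the neighbours of Snca are named outside this rule, after their values were seen. The groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined. The rest was chosen after: edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr), DESeq2 1.42.0 and limma-voom on the recovered reads, TMM scaling of the deposited values, and the symbol families.

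The other alternatives were quantile normalization, upper quartile scaling, no filter and a stricter filter on low values, pseudocounts of 0.1 and 10, a fold of at least 2, a fit of only the groups compared, and leaving out each library in turn. A group left with 1 library was assumed to vary like the others. A gene with no read in a group was given a fold bound from a floor of 3 counts over the group, and a gene with 1 to 3 reads a ratio with its exact 95% binomial interval. For the correlation of the single changes, unchanged groups were simulated 50 times against a shared LUC group.

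Tools were tested on simulated data with the spread of these libraries. Of genes with a simulated log2 change of 1 in CTNNB1 against LUC, limma called 74% and edgeR 73%, and of those with a change of 2, 98% and 99%; 8.02% and 7.03% of their calls were unchanged genes. DESeq2 called 78% and 99%, with 12.8% unchanged genes among its calls, and voom 73% and 97%, with 5.56%. For the interaction, limma called 24% and 88%. With no change simulated, limma called 2 genes in CTNNB1 against LUC and 0 in each of the other 5 comparisons. A list of shifted genes was called by camera at adjusted p = 4.9e-19 with the preset correlation and 0.0138 with an estimated one. Real lists had estimated correlations up to 0.678, so this does not decide between the settings.

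A search for genes with the same on and off libraries used a ratio of at least 3 and a value of at least 50 in the libraries with the gene on, settings chosen after the chromosome 1 segment was noticed. Pseudogene transcripts were aligned to parent transcripts with blastn 2.17.0 (e-value 1e-20). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the plots.

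Reads of members of multigene families and of copies (defensin, histone, Mptx, Cyp2c and Cyp2d genes, Eno1b, BC002163, Ifit1bl2 and C87977) are uncertain, since gene counts give no information on shared reads. Reads of the transgenes cannot be told from those of Ctnnb1 and Pik3ca. With groups of 2, a test for outlying libraries and a count over other splits of the libraries were not applicable.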

Results

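RNA was sequenced from organoids, cultures of intestinal epithelium in Matrigel, grown from the duodenum of adult transgenic C57/B6 mice. Doxycycline switched on 1 of 4 transgene sets, each with the red fluorescent protein tdTomato, and live positive cells were sorted. The control group expressed luciferase (LUC). The other groups expressed activated PIK3CA, the catalytic subunit of phosphoinositide 3-kinase; stabilized CTNNB1, the Wnt effector beta-catenin; or both together (CTNNB1_PIK3CA). Values are normalized read counts per gene. The recovered totals were 29304727 and 21058264 reads in LUC, 35422363 and 28000006 in PIK3CA, 30299356 and 26966541 in CTNNB1, and 33278572 and 29401557 in CTNNB1_PIK3CA. Of 47289 genes in the matrix, 26713 had a read in at least 1 library and 15581 passed the filter for testing. With 2 libraries per group the p-values measure only the spread between these libraries.

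Across genes, which are not independent replicates, the log2 values of the libraries of a group correlated at r = 0.977 in CTNNB1_PIK3CA and up to 0.989 in LUC. The first principal component held 39.7% of the variance, with the LUC libraries at scores of -52.2 and -63.2 and the CTNNB1_PIK3CA libraries at 56.1 and 31.7. The second component, with 20.2%, placed the PIK3CA libraries at 26.2 and 45.2 and the CTNNB1 libraries at -42.1 and -36.1. CTNNB1_PIK3CA replicate 2 came from a female animal, with 17540 normalized counts of Xist and 1.85 of the Y-linked Ddx3y. In the other 7 libraries, Xist lay between 1.70 and 24.6 and Ddx3y between 3465 and 5552. Mitochondrially encoded genes took 4.17% and 5.46% of the reads in LUC, 4.03% and 1.81% in PIK3CA, 4.57% and 2.75% in CTNNB1, and 2.27% and 2.07% in CTNNB1_PIK3CA.

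Reads at Pik3ca (chromosome 3, 32397671 to 32468486, GRCm38) averaged 2802 ± 37.5 normalized counts in LUC (SD, n = 2), 2726 ± 181 in CTNNB1, 9528 ± 1437 in PIK3CA and 8048 ± 2020 in CTNNB1_PIK3CA. Pik3ca rose against LUC by log2 1.76 (SE 0.17, limma adjusted p = 0.000981) in PIK3CA and by 1.50 in CTNNB1_PIK3CA. Ctnnb1, on chromosome 9, averaged 25242 ± 799 in LUC, 40212 ± 4637 in CTNNB1 and 41192 ± 2629 in CTNNB1_PIK3CA. It rose against LUC by log2 0.67 (SE 0.16, limma adjusted p = 0.0157) and 0.71 (limma adjusted p = 0.00791). The call in CTNNB1 was lost without LUC replicate 1 (limma adjusted p = 0.0767), LUC replicate 2 (0.110) or CTNNB1 replicate 2 (0.153), and that in CTNNB1_PIK3CA without LUC replicate 2 (0.0666). In PIK3CA, Ctnnb1 averaged 31013 ± 6514, and neither its difference from LUC (log2 0.28) nor that of CTNNB1_PIK3CA from PIK3CA (0.42) passed the threshold.

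**Figure D1:**
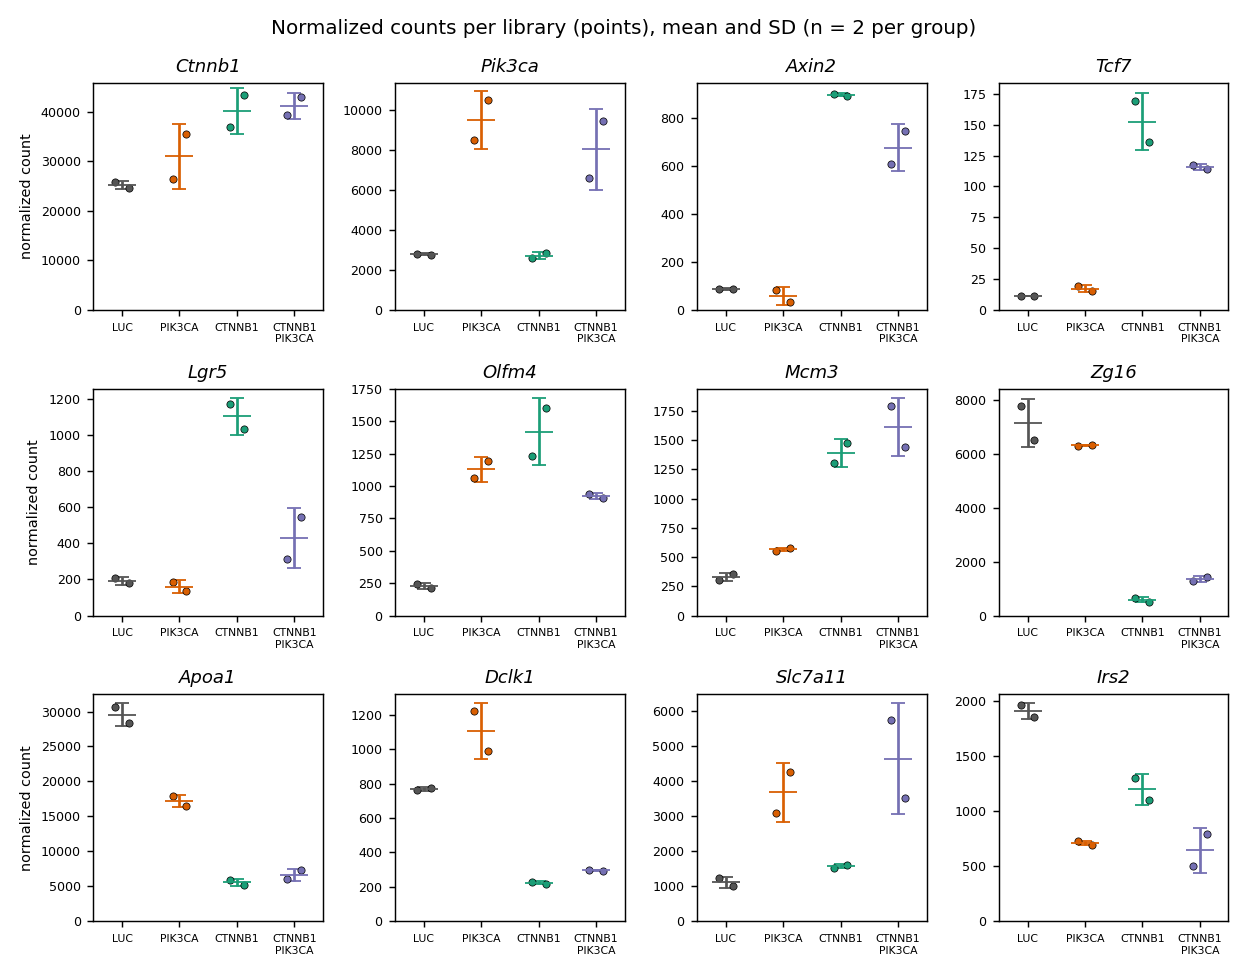
Normalized read counts (vertical axes) of 12 genes in the 4 groups, with points for the 2 libraries of a group, a horizontal bar for their mean and whiskers for the SD. Pik3ca was high in both groups with the PIK3CA transgene, Axin2 and Tcf7 in both groups with the CTNNB1 transgene, and Zg16 averaged 7145 in LUC against 585 in CTNNB1.

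The comparison of CTNNB1 with LUC asked which transcripts differed with stabilized beta-catenin. Most Wnt targets, crypt stem cell markers and cell cycle genes rose, and most markers of absorptive, goblet, tuft and enteroendocrine cells fell; as lists, their calls were lost with an estimated correlation (adjusted p = 0.146 to 0.274). Axin2, a feedback inhibitor of Wnt signalling, rose from 87.4 ± 2.47 normalized counts in LUC to 898 ± 5.18 in CTNNB1 (SD, n = 2 each), and the transcription factor gene Tcf7 rose from 11.4 ± 0.203 to 152 ± 23.2. Zg16, which encodes a lectin of goblet cell granules, fell from 7145 ± 886 to 585 ± 89.1, and the apolipoprotein gene Apoa1 of enterocytes fell by 2.41 on the log2 scale (SE 0.14, limma adjusted p = 4.51e-06). In all, 2397 of 15581 genes passed the limma threshold, 1233 higher and 1164 lower in CTNNB1.

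Of the 25 tested Wnt/beta-catenin targets, 17 rose and 1 fell, or 20 and 2 adjusted over the list alone, with a median log2 fold change of 1.16 (camera adjusted p = 3.79e-10). Among them were Rnf43 (2.26), Tcf7 (3.63), Ccnd1 (1.61) and Lgr5 (2.50), the receptor that marks crypt base stem cells. Of the 20 Lgr5 crypt base stem cell markers, 18 rose both over all genes and adjusted over the list alone (median 1.89, camera adjusted p = 3.54e-14), with Olfm4 at 2.62 and Slc12a2 at 2.04. Both calls were lost with an estimated correlation, at adjusted p = 0.248 and 0.146. The replication list of G1/S genes had 20 of 24 members higher (21 adjusted over the list alone; median 1.48, camera adjusted p = 5.28e-16), led by the helicase subunits Mcm3 (2.08), Mcm6 (1.87) and Mcm4 (2.16). The mitotic G2/M list had 21 of 24 higher (23 adjusted over the list alone; median 1.07, camera adjusted p = 4.57e-15), with Kif20a at 1.32 and Top2a at 1.30. Both cell cycle calls were lost, at adjusted p = 0.248 with an estimated correlation. Ribosome biogenesis genes rose in 20 of 25 cases (24 adjusted over the list alone; median 0.93, camera adjusted p = 2.27e-11; adjusted p = 0.426 with an estimated correlation), with Utp20 at 1.23 and Heatr1 at 1.10.

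All 29 tested absorptive enterocyte markers except 3 fell in CTNNB1, 26 over all genes and 27 adjusted over the list alone (median -1.15, camera adjusted p = 2.95e-17; adjusted p = 0.161 with an estimated correlation). Apoa4 (-2.06), Cyp3a11 (-1.93) and the keratin gene Krt20 (-1.65) were among them. Goblet cell markers fell in 14 of 20 cases (17 adjusted over the list alone; median -1.16, camera adjusted p = 1.08e-11; adjusted p = 0.248 with an estimated correlation), with Bcas1 at -2.27, Fer1l6 at -2.85 and Clca1 at -2.15. Tuft cell markers fell in 12 of 19 cases (15 adjusted over the list alone; median -1.34, camera adjusted p = 2.69e-10; adjusted p = 0.248 with an estimated correlation), with Dclk1 at -1.78 and Hck at -2.21. Enteroendocrine markers fell in 16 of 23 cases by both counts (median -1.16, camera adjusted p = 6.25e-09; adjusted p = 0.274 with an estimated correlation), with Isl1 at -1.95 and the serotonin synthesis gene Tph1 at -1.19. The Paneth list had 2 of 17 members lower, adjusted over all genes or over the list alone, Nupr1 (-1.31) and Clps (-0.80). Its median was -0.80 (camera adjusted p = 0.0294; adjusted p = 0.58 with an estimated correlation), -0.46 without CTNNB1 replicate 1, and -0.55 without Mptx1 and Mptx2, whose levels differed between the PIK3CA libraries too.

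3 further lists were called. FoxO targets, genes repressed when AKT is active, had 8 of 24 members lower (11 adjusted over the list alone; median -0.36, camera adjusted p = 0.014), with Cited2 at -1.21 and Cat at -0.98. Immediate early and dissociation stress genes had 7 of 21 lower and 1 higher (11 and 2 adjusted over the list alone; median -0.56, camera adjusted p = 0.00285), with Atf3 at -1.27. Interferon response genes had 4 of 21 lower by both counts (median -0.83, camera adjusted p = 0.0132), with Mx1 at -1.74. With an estimated correlation these calls were lost, at adjusted p = 0.58, 0.426 and 0.693. The Paneth call was also lost without LUC replicate 1 (camera adjusted p = 0.135) or CTNNB1 replicate 1 (0.0805), and the interferon call without LUC replicate 1 (0.0837) or CTNNB1 replicate 2 (0.166; median -0.39).

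The largest rises in CTNNB1 included Cyp2e1, a cytochrome P450 gene on chromosome 7, which had no read in LUC or PIK3CA and was at least 141-fold higher in CTNNB1, at 260 ± 51.4 normalized counts. The phospholipase gene Pla2g5 rose from 11.7 ± 2.26 to 437 ± 51.6, Myl9 from 12.3 ± 2.96 to 153 ± 36.5, Tnfrsf19 from 2.67 ± 2.33 to 60.9 ± 3.26 and Ascl2, a stem cell transcription factor, from 8.78 ± 6.32 to 72.7 ± 5.82. Cd244 rose 50.5-fold (95% exact binomial interval 17.0 to 247) over 3 reads in LUC, Itgad 17.5-fold (4.55 to 149) over 2 reads and Sla2 18.2-fold (2.96 to 752) over 1 read. Among the largest falls, Fhl1 went from 424 ± 53.1 to 25.5 ± 2.30, Chsy3 from 45.5 ± 13.5 to 2.39 ± 0.83, the dopamine transporter gene Slc6a3 from 65.9 ± 7.76 to 5.69 ± 0.383 and Slc34a2, a phosphate transporter gene, from 220 ± 49.1 to 25.6 ± 15.8. Onecut3 (-3.32), Slc28a2 (-3.31) and Tac4 (-3.20) also fell. Dpcr1 was 17.2-fold lower (interval 5.50 to 87.0), with 3 reads in CTNNB1. Mndal, on chromosome 1, had no read in CTNNB1 and was at least 83.2-fold lower than in LUC. It also differed between the PIK3CA libraries (96.9 and 1.07).

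The other 15 lists were not called in CTNNB1. Amino acid response and serine synthesis genes (ATF4 targets) had 5 of 25 members higher and 3 lower, or 8 and 3 adjusted over the list alone, with a median of 0.38 and camera adjusted p = 0.109. In the MAPK list, 6 of 22 members rose and 2 fell (7 and 7 adjusted over the list alone); its median was -0.10, its mean 0.03 and its test direction up (camera adjusted p = 0.829). The sterol synthesis list (median -0.09, camera adjusted p = 0.477) and the glycolysis list (median -0.01, 0.576) had no member past the threshold by either count, out of 25 and 20. Notch pathway genes had 4 of 15 higher and 1 lower by both counts (median 0.29, camera adjusted p = 0.0791), with Olfm4 and Nrarp (0.93) among the risers. Epithelial-mesenchymal transition and adhesion genes had 1 of 13 higher and 4 lower, or 2 and 6 adjusted over the list alone (median -0.13, camera adjusted p = 0.184). The p53 list had 3 of 20 higher and 5 lower, or 6 and 7 adjusted over the list alone (median -0.13, camera adjusted p = 0.477). The YAP and fetal epithelium list had 1 of 18 higher and 4 lower, or 2 and 5 adjusted over the list alone (median -0.44, camera adjusted p = 0.0731). The unfolded protein list had 2 of 20 lower by both counts, Dnajb9 and Ddit3 (median -0.06, camera adjusted p = 0.476). The duodenal-ileal list had 2 of 12 higher and 2 lower, or 3 and 2 adjusted over the list alone (median -0.33, camera adjusted p = 0.421).

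The stromal list had 4 tested members and the immune list 3, with none past the threshold by either count (limma; medians -0.02 and -0.22, camera adjusted p = 0.749 and 0.477). Of 4 tested endothelial markers, Tek fell by 1.89 on the log2 scale; adjusted over the list alone 1 rose and 1 fell (median -0.04, camera adjusted p = 0.778). The 14 mitochondrially encoded genes had a median of -0.58 (camera adjusted p = 0.477; median -0.92 without CTNNB1 replicate 1 and -0.23 without CTNNB1 replicate 2) and the 5 sex-linked genes one of -0.04 (camera adjusted p = 0.972), with none past the threshold by either count.

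edgeR on the recovered reads called 2335 genes, of which 2295 were called by both tools. Of the 2397 genes, 1032 changed at least 2-fold. The count fell to 988 without LUC replicate 1, to 1003 without LUC replicate 2 and to 815 without CTNNB1 replicate 2, and 58 of the 95 named called genes kept their call without each library in turn. Upper quartile scaling, which shifted the median of all genes by -0.10, called 1014 genes higher and 1676 lower out of 2690.

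The comparison of PIK3CA with LUC asked what differed with activated PIK3CA alone. Some genes of amino acid synthesis and transport, of the cell cycle and of ribosome biogenesis rose, and some Paneth cell markers and FoxO targets fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.421 to 0.423), and fry called 0 lists, with 11 at an unadjusted p under 0.05. Slc7a11, the cystine transporter gene, rose from 1111 ± 153 normalized counts in LUC to 3671 ± 834 in PIK3CA (SD, n = 2 each), or by log2 1.71 (SE 0.22, limma adjusted p = 0.00466). The stem cell marker Olfm4 rose from 229 ± 25.7 to 1128 ± 93.0. The Paneth defensin gene Defa24 fell from 104143 ± 6475 to 17055 ± 4221, and Irs2, an insulin receptor substrate gene, fell by 1.43 (SE 0.19, limma adjusted p = 0.00464). In all, 683 of 15581 genes passed the limma threshold, 373 higher and 310 lower in PIK3CA.

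Of 25 amino acid response and serine synthesis genes, 12 rose (15 rose and 2 fell adjusted over the list alone; median 0.86, camera adjusted p = 1.53e-06). They included the serine synthesis enzymes Phgdh (1.25) and Psat1 (1.70) and the mitochondrial enzyme Shmt2 (1.08). The replication list had 8 of 24 members higher (16 adjusted over the list alone; median 0.68, camera adjusted p = 1.55e-06), with Rrm2 at 1.21 and Mcm6 at 0.84, and the mitotic list 12 of 24 (20 adjusted over the list alone; median 0.60, camera adjusted p = 5.46e-10), with Plk1 at 0.91 and Aurka at 0.82. Unfolded protein response genes rose in 6 of 20 cases (8 adjusted over the list alone; median 0.30, camera adjusted p = 0.0012), with Creld2 at 0.83 and Calr at 0.61. These 4 calls were lost, each at adjusted p = 0.421 with an estimated correlation. Ribosome biogenesis genes rose in 4 of 25 cases (17 adjusted over the list alone; median 0.55, camera adjusted p = 7.06e-07; adjusted p = 0.423 with an estimated correlation), with Heatr1 at 0.81 and Rrp9 at 1.12. In the YAP and fetal epithelium list, 4 of 18 members rose and 1 fell (6 and 1 adjusted over the list alone; median 0.46, camera adjusted p = 0.0153; adjusted p = 0.423 with an estimated correlation), with Anxa1 at 1.46 and Cyr61 at -1.19.

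Of 17 tested Paneth markers, 6 fell in PIK3CA (13 adjusted over the list alone; median -2.02, or -1.96 without Mptx1 and Mptx2; camera adjusted p = 3.33e-10), among them Itln1 (-1.50), Clps (-1.50) and the lysozyme gene Lyz1 (-1.85). Goblet markers fell in 4 of 20 cases (10 adjusted over the list alone; median -0.52, camera adjusted p = 3.39e-06), with Bcas1 at -0.83 and Tpsg1 at -1.10. Enterocyte markers fell in 5 of 29 cases (7 adjusted over the list alone; median -0.32, camera adjusted p = 0.000215), with Cyp3a11 at -1.12 and the peptide transporter gene Slc15a1 at -1.16. FoxO targets fell in 7 of 24 cases (11 adjusted over the list alone; median -0.59, camera adjusted p = 2.49e-07), with Cited2 at -1.19, Cat at -0.85 and Ccng2 at -0.84. The Lgr5 stem cell list had 2 of 20 members higher, Olfm4 and Cdk6 (0.65), and the water channel gene Aqp4 lower at -0.99 (5 and 1 adjusted over the list alone; median 0.37, camera adjusted p = 0.0124). These 5 calls were lost, each at adjusted p = 0.421 with an estimated correlation. Tuft markers had no member past the limma threshold by either count, yet a median of 0.42 (camera adjusted p = 0.00384; adjusted p = 0.484 with an estimated correlation), with Dclk1 at 0.51 and Avil at 0.53. The tuft median was 0.18 without PIK3CA replicate 1 and 0.64 without PIK3CA replicate 2.

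Mitochondrially encoded genes had a median of -1.02 in PIK3CA, with mt-Co2 called among 14 by both the count over all genes and that adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.423 with an estimated correlation). The stress gene list had 2 of 21 members higher, Hsph1 (1.23) and Ier3 (1.02), against 2 higher and 8 lower adjusted over the list alone (median -0.49, camera adjusted p = 0.0124; adjusted p = 0.423 with an estimated correlation). Leaving out PIK3CA replicate 1 ended the call of the stem cell list (camera adjusted p = 0.157) and of the tuft list (0.205). The mitochondrial median was -1.65 without PIK3CA replicate 1, and the call was lost without PIK3CA replicate 2 (0.208; median -0.51), and the stress call without LUC replicate 1 (0.136).

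Wnt targets were not called in PIK3CA, where Ccnd1 (0.88) alone of 25 rose by either count; the list's median of -0.06 differed in sign from its mean of 0.07 and its test direction, up (camera adjusted p = 0.697). Enteroendocrine markers had 1 of 23 members lower by both counts, Isl1 at -0.91 (median -0.18, camera adjusted p = 0.241; median -0.51 without PIK3CA replicate 1 and 0.17 without PIK3CA replicate 2). In the MAPK list, 4 of 22 members rose, or 7 rose and 2 fell adjusted over the list alone (median 0.25, or 0.12 without PIK3CA replicate 2; camera adjusted p = 0.0915), with the growth factor gene Ereg at 1.62 and Spry4 at 1.47. The Notch list (median -0.06, mean 0.16, camera adjusted p = 0.675) and the duodenal list (median -0.03, mean 0.07, camera adjusted p = 0.697) also had means and test directions, up, that differed in sign from the medians. Other uncalled lists had camera adjusted p from 0.0915 for glycolysis to 0.86 for the sex-linked genes.

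The largest rises in PIK3CA included Abca12, a lipid transporter gene, from 20.9 ± 5.10 to 150 ± 4.42 normalized counts, Samd5 from 4.50 ± 2.29 to 38.0 ± 5.28, Cdc42ep1 from 103 ± 7.29 to 393 ± 112 and Phlda2 from 20.1 ± 8.20 to 68.9 ± 4.12. Slc24a5 (log2 2.49) rose as well, and Sla2 rose 25.2-fold (interval 4.21 to 1026) over 1 read in LUC. BC002163 rose from 23.0 ± 12.2 to 421 ± 34.4 and Eno1b from 32.8 ± 0.313 to 364 ± 110. Both are uncertain, since BC002163 is a processed pseudogene with 99.4% identity to Ndufs5 and Eno1b is a copy of Eno1. Among the falls were Dclk3, from 444 ± 103 to 53.9 ± 17.1, Ciita, the activator of class II antigen genes, from 39.6 ± 3.12 to 3.76 ± 5.32, and Chsy3, Hapln3 (-2.54) and Defa22 (-3.18). Rab6b was 28.0-fold lower (interval 7.29 to 238), with 2 reads in PIK3CA. Cyp2c37 (-3.73), Ifit1bl2 (-2.87) and C87977 (-2.64) fell too, but belong to families of similar genes and are uncertain, as are the defensin genes.

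The limma count of 683 compares with 667 by edgeR, 656 of them shared, and 253 of the 683 changed at least 2-fold. The count dropped to 70 without LUC replicate 1, 32 without LUC replicate 2, 230 without PIK3CA replicate 1 and 53 without PIK3CA replicate 2, rose to 1442 and 1429 without CTNNB1_PIK3CA replicate 1 and replicate 2, and was 1395 with DESeq2 and 1718 in a fit of only the LUC and PIK3CA libraries. Of 74 named called genes, 7 kept their call without each library in turn: Abca12, BC002163, Dclk3, Eno1b, Ereg, Olfm4 and Pik3ca. Upper quartile scaling called 279 genes higher and 461 lower out of 740.

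The CTNNB1_PIK3CA comparison with LUC asked what differed with both transgenes. Most Wnt targets, stem cell markers, replication genes, ribosome biogenesis genes and amino acid response genes rose, and most enterocyte, goblet and tuft markers and FoxO targets fell; as lists, their calls were lost with an estimated correlation (adjusted p = 0.334 to 0.393). Axin2 rose from 87.4 ± 2.47 normalized counts in LUC to 677 ± 97.4 in CTNNB1_PIK3CA (SD, n = 2 each). Psat1 rose by log2 2.34 (SE 0.24, limma adjusted p = 0.000223), and the cyclin gene Ccnd2 rose by 2.69 (SE 0.21, limma adjusted p = 4.09e-05). Zg16 fell to 1359 ± 108 and Irs2 fell by 1.60 (SE 0.19, limma adjusted p = 0.00027). In all, 4340 of 15581 genes passed the limma threshold, 2254 higher and 2086 lower in CTNNB1_PIK3CA.

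Of 25 Wnt targets, 18 rose and 1 fell (19 and 1 adjusted over the list alone; median 1.09, camera adjusted p = 2.74e-07; adjusted p = 0.393 with an estimated correlation), with Ccnd1 at 2.07, Tcf7 at 3.24 and Axin2 at 2.93. Of 20 stem cell markers, 18 rose and 1 fell by both counts, that is also adjusted over the list alone (median 1.29, camera adjusted p = 3.32e-09; adjusted p = 0.334 with an estimated correlation), with Olfm4 at 2.01 and Cdk6 at 1.86. The replication list had 21 of 24 higher by both counts (median 1.57, camera adjusted p = 2.44e-13), with Mcm3 at 2.29 and Mcm2 at 2.30, and the mitotic list 21 of 24 (22 adjusted over the list alone; median 0.95, camera adjusted p = 1.3e-09), with Plk1 at 1.43. Ribosome biogenesis genes rose in 22 of 25 cases (24 adjusted over the list alone; median 1.13, camera adjusted p = 9.83e-11), with Utp20 at 1.46 and Polr1b at 1.85. Amino acid response genes rose in 17 of 25 cases and fell in 1 (19 and 3 adjusted over the list alone; median 1.06, camera adjusted p = 2.15e-06), with Phgdh at 1.65, Slc7a11 at 2.02 and Psph at 1.78. These 4 calls were lost, each at adjusted p = 0.393 with an estimated correlation.

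Enterocyte markers fell in 22 of 29 cases (23 adjusted over the list alone; median -0.87, camera adjusted p = 1.3e-09), with Apoa1 at -2.16 and Apoa4 at -1.49. Goblet markers fell in 15 of 20 cases (18 adjusted over the list alone; median -1.30, camera adjusted p = 3.81e-09), with Zg16 at -2.39 and Bcas1 at -2.23. Tuft markers fell in 13 of 19 cases (15 adjusted over the list alone; median -0.98, camera adjusted p = 2.16e-07), with Dclk1 at -1.38 and Alox5ap at -2.02. FoxO targets fell in 17 of 24 cases (1 rose and 17 fell adjusted over the list alone; median -0.68, camera adjusted p = 2.25e-05), with Cat at -1.53 and Cited2 at -1.63. These 4 calls were lost, each at adjusted p = 0.393 with an estimated correlation. Enteroendocrine markers fell in 9 of 23 cases (10 adjusted over the list alone; median -0.80, camera adjusted p = 0.00163; adjusted p = 0.536 with an estimated correlation), with Isl1 at -1.54 and Scg2 at -1.56. Paneth markers fell in 5 of 17 cases by both counts (median -1.09, or -0.82 without Mptx1 and Mptx2; camera adjusted p = 0.0029; adjusted p = 0.458 with an estimated correlation), with Clps at -1.20 and Defa20 at -2.73. Interferon genes fell in 8 of 21 cases (1 rose and 10 fell adjusted over the list alone; median -0.72, camera adjusted p = 0.0174; adjusted p = 0.623 with an estimated correlation), with Ddx58 at -0.86 and Ifit1 at -1.80. The Paneth call was lost without CTNNB1_PIK3CA replicate 1 (camera adjusted p = 0.0932; median -0.47) and the interferon call without LUC replicate 1 (0.103) or CTNNB1_PIK3CA replicate 1 (0.0917; median -0.33).

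Mitochondrially encoded genes had a median of -1.84 in CTNNB1_PIK3CA, with 3 of 14 lower and 2 adjusted over the list alone (camera adjusted p = 0.00752; adjusted p = 0.458 with an estimated correlation). Among them, mt-Co2 fell from 603 ± 119 normalized counts to 136 ± 40.6. The other 14 lists were not called, with camera adjusted p from 0.0676 for the MAPK list, of which 9 of 22 members rose and 2 fell, to 0.909 for the endothelial list. In the MAPK list, Etv4 rose by log2 2.10 and Etv5 by 1.10. The YAP and fetal list had a median of -0.02, a mean of 0.15 and a test direction of up (camera adjusted p = 0.519). The stress list had Hsph1 higher at 1.80 and Klf4 lower at -1.52 (camera adjusted p = 0.0742).

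The largest rises in CTNNB1_PIK3CA again included Cyp2e1, at least 74.2-fold above LUC, and Pla2g5, at 278 ± 53.9 normalized counts. Tcf7 reached 116 ± 2.62 and Tnfrsf19 28.3 ± 12.3. The replication-dependent histone genes Hist1h4b (16.2 ± 4.55 in LUC, 456 ± 54.3 in CTNNB1_PIK3CA), Hist1h4f (28.4 ± 11.7 and 553 ± 45.3) and Hist1h3c (22.5 ± 21.6 and 299 ± 30.1) rose, and are uncertain as members of families of near-identical genes. Cd244 rose 44.8-fold (interval 15.1 to 219) over 3 reads in LUC, Itgad 16.4-fold (4.27 to 139) over 2 reads and Sla2 23.8-fold (3.97 to 968) over 1 read. Among the largest falls, Fhl1 dropped to 23.1 ± 17.0, Dnm3 went from 32.8 ± 0.313 to 1.85 ± 2.62 and Dnase1 from 142 ± 67.0 to 10.0 ± 5.05. Myo3a (-3.52), Chsy3 (-3.84) and Cyp2d34 (-3.45, of a family of similar genes) fell, and Mptx1 fell from 6718 ± 1203 to 14.8 ± 9.16. Dock2 was 60.5-fold lower (interval 16.3 to 508), with 2 reads in CTNNB1_PIK3CA. Snca, the alpha-synuclein gene, and Mndal had no read there and were at least 16.3-fold and 88.8-fold lower than in LUC. Mndal and Mptx1 also differed within PIK3CA, and Snca had reads in both single groups, so these falls may not come from the transgenes.

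edgeR called 4231 genes, of which 4158 were shared with the 4340 of limma, and 1759 of the 4340 changed at least 2-fold. The limma count fell to 2543 without LUC replicate 1, to 1715 without LUC replicate 2 and to 2364 without CTNNB1_PIK3CA replicate 1, and 77 of 112 named called genes kept their call without each library in turn. Upper quartile scaling shifted the median of all genes by -0.11 and called 1802 genes higher and 2753 lower out of 4555. Over the 6 comparisons, 0 of the 75 called list medians had another sign under upper quartile, TMM or quantile scaling, and 3 had another sign without 1 library.

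**Figure D2:**
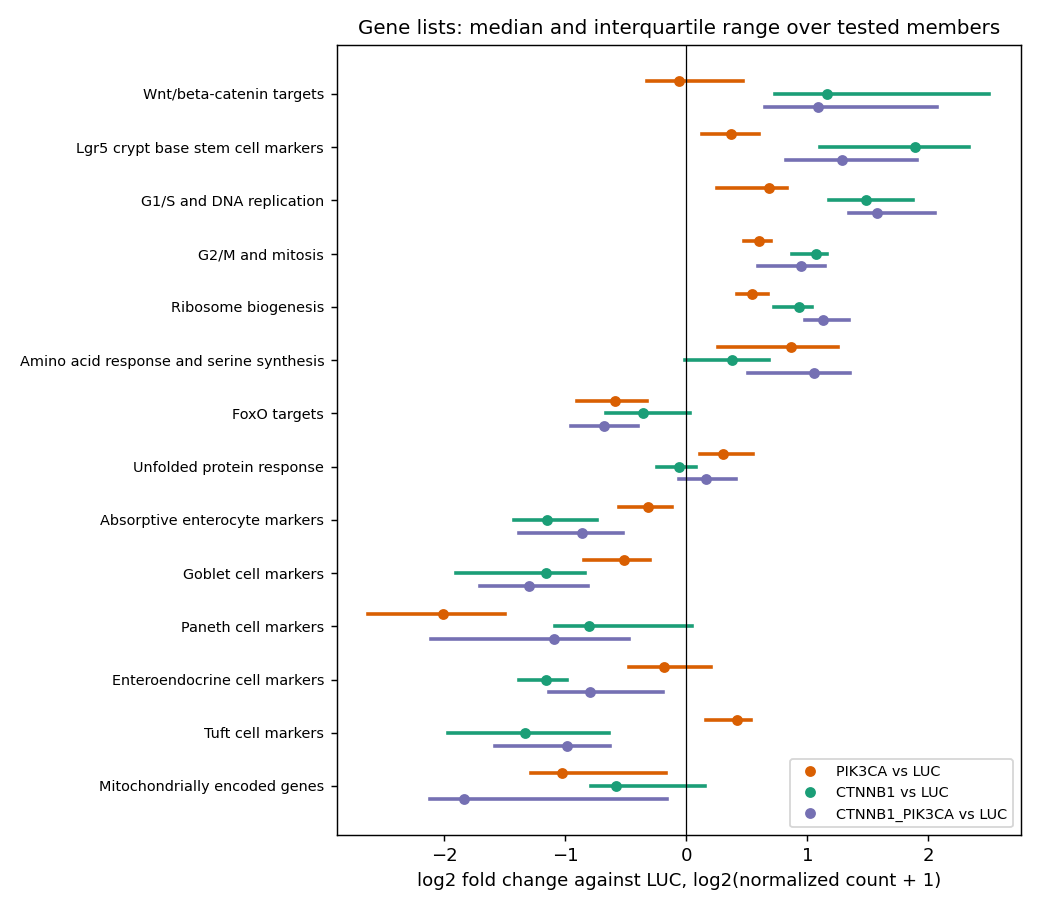
Log2 fold change against LUC (horizontal axis) of 14 gene lists (vertical axis) in the 3 other groups, with points for the median over tested members and lines for the interquartile range. Wnt targets had medians of 1.16 in CTNNB1 and 1.09 in CTNNB1_PIK3CA against -0.06 in PIK3CA, and Paneth markers had their lowest median, -2.02, in PIK3CA.

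Genes higher than in LUC in both CTNNB1 and PIK3CA numbered 241, those lower 170, and 6 were called in opposite directions. Fold changes correlated across all genes at r = 0.558. In 50 simulations of unchanged groups with a shared LUC group, the mean was 0.528 and the highest 0.555. The covariance was 0.243, against a highest of 0.0860. An error in LUC could raise these. Olfm4 and Phgdh were among the genes higher in both, and Cited2 and Cat among those lower in both.

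The comparison of CTNNB1_PIK3CA with CTNNB1 asked what differed once activated PIK3CA was added. The amino acid response genes Slc7a11, Trib3 and Nupr1 rose, as did the annexin genes Anxa1 and Anxa10, and the FoxO target Txnip fell. Slc7a11 rose from 1571 ± 62.2 normalized counts in CTNNB1 to 4633 ± 1577 in CTNNB1_PIK3CA (SD, n = 2 each; log2 1.52, SE 0.22, limma adjusted p = 0.03). Anxa1 rose from 147 ± 29.6 to 465 ± 71.8 and Ereg from 188 ± 18.8 to 502 ± 56.4. Txnip, an inhibitor of thioredoxin, fell from 22030 ± 128 to 11808 ± 284 and mt-Co2 from 445 ± 96.5 to 136 ± 40.6. In all, 35 of 15581 genes passed the limma threshold, 25 higher and 10 lower. Without CTNNB1_PIK3CA replicate 2, the female library, most calls were lower.

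Of 25 amino acid response genes, 3 rose, Nupr1 (0.84), Slc7a11 and Trib3 (1.31), and 17 rose adjusted over the list alone (median 0.67, camera adjusted p = 8.64e-11). FoxO targets had 1 of 24 members lower, Txnip, and 8 adjusted over the list alone (median -0.40, camera adjusted p = 0.000455). The YAP and fetal list had 2 of 18 higher, Anxa1 and Anxa10 (1.52), and 6 adjusted over the list alone (median 0.37, camera adjusted p = 0.00063). The MAPK list had 1 of 22 higher, Ereg, and 4 adjusted over the list alone (median 0.25, camera adjusted p = 0.00321). Enterocyte markers had 1 of 29 higher, Rbp2 (0.95), and 9 adjusted over the list alone (median 0.26, camera adjusted p = 0.00141). Stem cell markers had 0 of 20 past the limma threshold, with Lgr5 at -1.41 (SE 0.26, limma adjusted p = 0.0503), and 4 lower adjusted over the list alone (median -0.40, camera adjusted p = 0.00063). The unfolded protein list had no member past the limma threshold and 2 of 20 higher adjusted over the list alone (median 0.26, camera adjusted p = 0.000455), with Hspa5 at 0.51. Mitochondrially encoded genes had mt-Co2 lower among 14, and 2 adjusted over the list alone (median -1.17, camera adjusted p = 0.00063). These 8 calls were lost, each at adjusted p = 0.531 with an estimated correlation. Enteroendocrine markers had no member past the limma threshold and 4 of 23 higher adjusted over the list alone (median 0.37, camera adjusted p = 0.00063; adjusted p = 0.584 with an estimated correlation), with Cck at 0.92. Ribosome biogenesis genes had none of 25 past it by either count (median 0.21, camera adjusted p = 0.0184; adjusted p = 0.705 with an estimated correlation). Without CTNNB1_PIK3CA replicate 1 the median was -0.15 for FoxO targets, -0.08 for ribosome biogenesis and 0.78 for the YAP list, and without CTNNB1_PIK3CA replicate 2 it was 0.44 for ribosome biogenesis and -0.01 for the YAP list. Without CTNNB1 replicate 2 the enterocyte and MAPK medians were both 0.16, and without CTNNB1 replicate 1 the mitochondrial one was -0.65.

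The named genes of this comparison also included Dner (15.2 ± 1.02 in CTNNB1, 72.2 ± 1.41 in CTNNB1_PIK3CA), Ptpn22 (34.3 ± 7.73 and 143 ± 17.9), Bcl2l15 (202 ± 13.8 and 844 ± 357), Ddah1 (125 ± 3.69 and 391 ± 97.5) and Pak3 (96.4 ± 1.54 and 265 ± 31.5), which rose. Kctd14 (1320 ± 264 and 527 ± 199), Klhl24 (1237 ± 120 and 605 ± 88.8) and Cyp4v3 (5375 ± 139 and 2767 ± 21.2) fell, and Snca was at least 12.5-fold lower. Zg16 rose by log2 1.22. The 18 lists without a call had camera adjusted p from 0.0685, for the mitotic and p53 lists, to 0.743 for the duodenal list; the immune list had a median and mean below 0 with a test direction of up.

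edgeR called 51 genes, 35 of them shared, and 2414 genes had an unadjusted limma p under 0.05. The limma count was 13 without LUC replicate 1 and 13 without LUC replicate 2, 63 without PIK3CA replicate 2, 14 without CTNNB1 replicate 1, 6 without CTNNB1 replicate 2 and 590 without CTNNB1_PIK3CA replicate 2. With other processing the count was between 16 and 402, as listed below. Only Pik3ca, of 21 named called genes, kept its call without each library in turn. The list calls lost in that way had camera adjusted p up to 0.388 (YAP and fetal list, without CTNNB1_PIK3CA replicate 2). Without CTNNB1 replicate 2, the stem cell (0.0616), enterocyte (0.0563), ribosome biogenesis (0.0635) and MAPK (0.0616) calls were lost; without CTNNB1_PIK3CA replicate 2, the enterocyte (0.127) and MAPK (0.242) calls were. The ribosome biogenesis list turned direction without CTNNB1_PIK3CA replicate 1 (0.358), and the interferon list, not called with all libraries, was called higher (0.019). The number of lists called went from 10 to 6 without CTNNB1 replicate 2 and to 16 without CTNNB1_PIK3CA replicate 1.

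The comparison of CTNNB1_PIK3CA with PIK3CA asked what differed once stabilized beta-catenin was added. Most replication genes and some Wnt targets rose, and some tuft, goblet and enterocyte markers fell; as lists, their calls were lost with an estimated correlation (adjusted p = 0.166 to 0.419). Axin2 rose from 57.3 ± 37.1 normalized counts in PIK3CA to 677 ± 97.4 in CTNNB1_PIK3CA (SD, n = 2 each; log2 3.69, SE 0.36, limma adjusted p = 0.000733). Slc1a3, a glutamate transporter gene, rose from 37.7 ± 9.33 to 324 ± 107. Dclk1, a tuft cell kinase gene, fell by 1.89 (SE 0.16, limma adjusted p = 0.000333), and Zg16 fell from 6299 ± 13.2 to 1359 ± 108. In all, 298 of 15581 genes passed the limma threshold, 159 higher and 139 lower. Without CTNNB1_PIK3CA replicate 2 most calls were lower.

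Of 25 Wnt targets, 10 rose (18 rose and 1 fell adjusted over the list alone; median 1.11, camera adjusted p = 3.25e-13), with Tcf7 at 2.70 and Rnf43 at 1.46. Stem cell markers rose in 7 of 20 cases (15 adjusted over the list alone; median 0.87, camera adjusted p = 2.63e-11), with Slc12a2 at 1.64. Replication genes rose in 15 of 24 cases (22 adjusted over the list alone; mean 0.99, camera adjusted p = 4.82e-19), with Mcm3 at 1.50 and Uhrf1 at 1.43. Tuft markers fell in 10 of 19 cases (18 adjusted over the list alone; median -1.38, camera adjusted p = 3.74e-18), with Hck at -2.15 and Alox5ap at -2.53. Enterocyte markers fell in 12 of 29 cases (19 adjusted over the list alone; median -0.59, camera adjusted p = 3.41e-12), with Apoa1 at -1.38. These 5 calls were lost, each at adjusted p = 0.166 with an estimated correlation. Goblet markers fell in 4 of 20 cases (1 rose and 10 fell adjusted over the list alone; median -0.64, camera adjusted p = 1.33e-07; adjusted p = 0.419 with an estimated correlation), with Clca1 at -1.52. The goblet median was -0.36 without CTNNB1_PIK3CA replicate 1 and -0.997 without CTNNB1_PIK3CA replicate 2.

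The mitotic list had no member past the limma threshold in CTNNB1_PIK3CA against PIK3CA and 5 of 24 higher adjusted over the list alone (median 0.31, camera adjusted p = 6.64e-05), with Kif20a at 0.59. The Paneth list had 1 of 17 higher by both counts, Itln1 at 1.79 (median 1.22, camera adjusted p = 0.00415). The duodenal-ileal list had 0 of 12 past the limma threshold by either count (median -0.35, camera adjusted p = 0.0499). These 3 calls were lost, each at adjusted p = 0.517 with an estimated correlation. Enteroendocrine markers had 1 of 23 lower, Scg2 at -1.16, and 4 adjusted over the list alone (median -0.50, camera adjusted p = 4.93e-05), ribosome biogenesis genes 2 of 25 higher and 18 adjusted over the list alone (median 0.58, camera adjusted p = 4.26e-10), and interferon genes 4 of 21 lower and 8 adjusted over the list alone (median -0.96, camera adjusted p = 1.99e-06), with Ifit1 at -2.58. These 3 calls were lost, each at adjusted p = 0.464 with an estimated correlation. Amino acid response genes had none of 25 past the limma threshold by either count (median 0.25, camera adjusted p = 0.0199; adjusted p = 0.521 with an estimated correlation). Without CTNNB1_PIK3CA replicate 1 the median was -0.38 for interferon genes and 0.28 for ribosome biogenesis, and the enteroendocrine median was -0.23 and -0.85 without PIK3CA replicate 1 and replicate 2. Without PIK3CA replicate 2, the Paneth (camera adjusted p = 0.182), mitotic (0.182; median 0.15) and duodenal (0.199) calls were lost, and without CTNNB1_PIK3CA replicate 2 the Paneth call (0.153; median 0.54) was. The amino acid call was lost without PIK3CA replicate 1 (0.284; median 0.08) or CTNNB1_PIK3CA replicate 1 (0.703; median -0.01), its median was 0.44 without CTNNB1_PIK3CA replicate 2, and the duodenal call also without CTNNB1_PIK3CA replicate 1 (0.523), CTNNB1 replicate 1 (0.0596) or CTNNB1 replicate 2 (0.0596).

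Cyp2e1 was at least 95.6-fold higher in CTNNB1_PIK3CA than in PIK3CA. Rgcc (7.87 ± 6.59 and 188 ± 23.5), Pla2g5 (13.8 ± 2.89 and 278 ± 53.9), Ptpro (3.10 ± 3.20 and 31.6 ± 9.43) and Dsel (4.53 ± 1.86 and 36.9 ± 4.05) rose. Cd244 rose 171-fold (interval 30.3 to 6788) over 1 read in PIK3CA, Myo1g 28.0-fold (9.28 to 138) over 3 reads and Rab6b 17.0-fold (4.38 to 146) over 2 reads. Clca4a (194 ± 10.5 and 33.4 ± 20.8), Cyp1a1 (81.9 ± 2.41 and 15.5 ± 14.7), Sprr1a (850 ± 357 and 153 ± 100.0), Alox5 (-2.67) and Fhl1 (-2.62) fell, as did the uncertain copies BC002163 (-4.70) and Eno1b (-3.50). Dock2 was 45.5-fold lower (interval 12.2 to 382), with 2 reads in CTNNB1_PIK3CA, and Snca was at least 10.8-fold lower. The 15 lists without a call had camera adjusted p from 0.0528, for the unfolded protein list, to 0.991 for the stress, stromal and endothelial lists. Signs differed between median, mean and test in the sterol (0.01, -0.03, down), MAPK (-0.02, 0.09, up), stress (-0.08, -0.02, up), stromal (0.08, -0.02, up) and endothelial (0.12, -0.25, down) lists.

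edgeR called 322 genes, 291 of them shared with limma, and 175 of the 298 changed at least 2-fold. The limma count was 189 without LUC replicate 1, 189 without LUC replicate 2, 86 without PIK3CA replicate 1, 77 without PIK3CA replicate 2, 153 without CTNNB1_PIK3CA replicate 1 and 894 without CTNNB1_PIK3CA replicate 2, and was 742 with DESeq2 and 195 in a fit of only the PIK3CA and CTNNB1_PIK3CA libraries. Of 54 named called genes, 29 kept their call without each library in turn.

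The interaction compared the change in CTNNB1_PIK3CA with the sum of the single log2 changes. Olfm4 averaged 229 ± 25.7 normalized counts in LUC, 1128 ± 93.0 in PIK3CA and 1419 ± 260 in CTNNB1, but 923 ± 21.7 in CTNNB1_PIK3CA (SD, n = 2 each), which lies below that sum by log2 -2.90 (SE 0.24, limma adjusted p = 0.000702). The glucose transporter family gene Slc5a4b (1281 ± 101 in LUC, 531 ± 39.7 in PIK3CA, 188 ± 17.4 in CTNNB1 and 313 ± 5.82 in CTNNB1_PIK3CA) lay above it by 2.00 (SE 0.23, limma adjusted p = 0.0103). Pck1 lay above by 1.84, Slc15a1 by 1.69, Plk2 by 1.40, Zg16 by 1.40, Nupr1 by 1.29 and Clec2h by 1.17. Ppp1r3b lay below by -1.40, as did Eno1b by -3.20, with its reads uncertain. Of 15581 genes, 14 passed the limma threshold, 9 above and 5 below. They included 4 predicted gene models: Gm8210 (6.50), Gm13456 (1.76), Gm10036 (-4.71) and Gm8989 (-2.13). Gm8210 was at most 8.57 outside LUC, so its falls could not add. Gm10036 was high in PIK3CA alone.

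Camera called 11 lists in the interaction at the preset correlation and 0 with an estimated one, and fry called 0, with 3 and 6 at an unadjusted p under 0.05. Mitotic genes had no member past the limma threshold over all genes and 22 of 24 below the sum adjusted over the list alone (median -0.76, camera adjusted p = 2.6e-16; adjusted p = 0.355 with an estimated correlation), with Bub1b at -1.01 and Aurkb at -1.03. Replication genes had none over all genes and 1 of 24 below adjusted over the list alone (median -0.57, camera adjusted p = 7.01e-05; adjusted p = 0.512 with an estimated correlation). Stem cell markers had 1 of 20 below, Olfm4, and 9 adjusted over the list alone (median -0.56, camera adjusted p = 6.98e-08; adjusted p = 0.332 with an estimated correlation). Enterocyte markers had 1 of 29 above, Slc15a1, and 12 adjusted over the list alone (median 0.50, camera adjusted p = 1.68e-11; adjusted p = 0.332 with an estimated correlation). Paneth markers had 1 of 17 above, Nupr1, and 4 adjusted over the list alone (median 1.52, camera adjusted p = 3.76e-09; adjusted p = 0.355 with an estimated correlation). Goblet markers had 1 of 20 above, Zg16, and 4 adjusted over the list alone (median 0.61, camera adjusted p = 1e-08; adjusted p = 0.398 with an estimated correlation). The goblet median was 0.999 without CTNNB1_PIK3CA replicate 1, and without CTNNB1_PIK3CA replicate 2 the goblet median was 0.38 and the replication median -0.36.

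Enteroendocrine markers had none above the limma threshold and 1 of 23 adjusted over the list alone (median 0.71, camera adjusted p = 9.06e-06), stress genes none and 2 of 21 (median 0.46, camera adjusted p = 0.000284), and p53 targets 1 of 20, Plk2, and 2 adjusted over the list alone (median 0.22, camera adjusted p = 0.0326). These 3 calls were lost, each at adjusted p = 0.493 with an estimated correlation. Ribosome biogenesis genes (median -0.33, camera adjusted p = 0.000892; adjusted p = 0.831 with an estimated correlation) and FoxO targets (median 0.29, camera adjusted p = 0.0235; adjusted p = 0.767 with an estimated correlation) had no member past the limma threshold by either count, with Heatr1 at -0.49 and Bcl6 at 0.85. The stress median was 0.73 and 0.07 and the ribosome biogenesis median -0.61 and -0.03 without CTNNB1_PIK3CA replicate 1 and replicate 2, and the enteroendocrine median was 0.39 without PIK3CA replicate 2. Leaving out 1 library ended the FoxO call (LUC replicate 2, camera adjusted p = 0.081; PIK3CA replicate 2, 0.0808; CTNNB1 replicate 2, 0.0661; CTNNB1_PIK3CA replicate 2, 0.613, median 0.19). It ended the p53 call without LUC replicate 2 (0.342; median 0.14), PIK3CA replicate 2 (0.111; median 0.12), CTNNB1 replicate 2 (0.108) or CTNNB1_PIK3CA replicate 1 (0.0679), and the ribosome biogenesis call without CTNNB1_PIK3CA replicate 2 (0.765).

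The 17 lists without an interaction call had camera adjusted p from 0.111 for the Wnt targets to 0.968 for the amino acid response list, whose median was -0.08 and mean 0.00. The adhesion list (median -0.03, mean 0.05, up) and the endothelial list (median -0.04, mean -0.01, up) also differed in sign between the measures. edgeR called 16 genes, 14 of them shared, and 1141 genes had an unadjusted limma p under 0.05. The limma count was 5 without LUC replicate 1, 1 without LUC replicate 2, 5 and 6 without PIK3CA replicate 1 and replicate 2, 5 without CTNNB1 replicate 2, and 64 and 22 without CTNNB1_PIK3CA replicate 1 and replicate 2; it was 78 with DESeq2, 41 with no filter and 3 with voom. Of the 10 named called genes, Olfm4 alone kept its call without each library in turn.

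**Figure D3:**
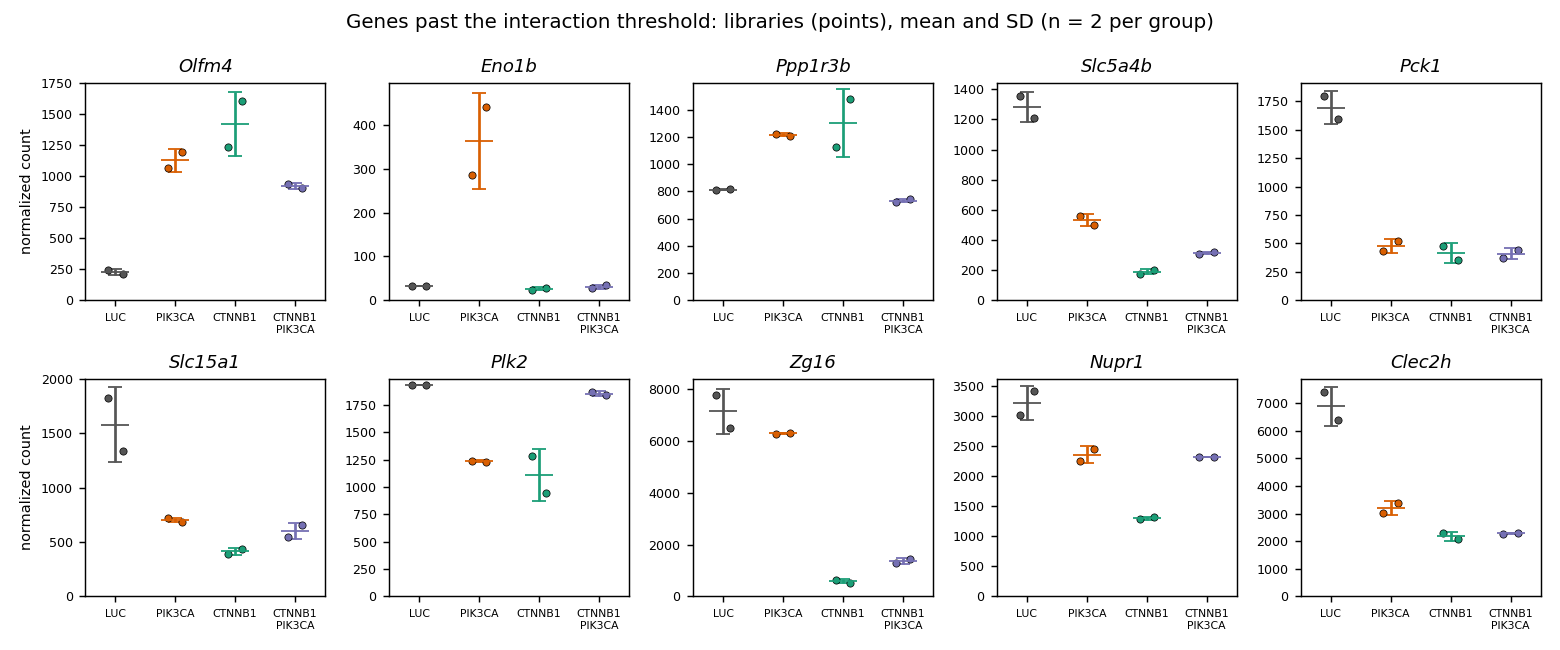
Normalized read counts (vertical axes) of the 10 named genes past the interaction threshold in the 4 groups, with points for the libraries, a horizontal bar for their mean and whiskers for the SD. Olfm4 averaged 1128 in PIK3CA and 1419 in CTNNB1 but 923 in CTNNB1_PIK3CA.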

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

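The tests of the explanations weighed here, and the choice of the patterns, were made after the results were seen.

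The interaction test set apart results that differed from the sum of the single changes. Among named genes, Slc5a4b (2.00), Pck1 (1.84), Slc15a1 (1.69), Plk2 (1.40), Zg16 (1.40), Nupr1 (1.29) and Clec2h (1.17) lay above the sum on the log2 scale, and Eno1b (-3.20), Olfm4 (-2.90) and Ppp1r3b (-1.40) below it. Among lists, the median interaction was 1.52 for Paneth, 0.61 for goblet, 0.71 for enteroendocrine and 0.50 for enterocyte markers, 0.29 for FoxO targets, 0.22 for p53 targets and 0.46 for stress genes. It was -0.56 for stem cell markers, -0.57 for replication genes, -0.76 for mitotic genes and -0.33 for ribosome biogenesis genes. Some medians moved by over 1.5 times without 1 library: to 0.73, 0.999 and -0.61 for stress, goblet and ribosome biogenesis genes without CTNNB1_PIK3CA replicate 1, and to 0.07, 0.38, -0.03, -0.36 and 0.19 for stress, goblet, ribosome biogenesis, replication and FoxO genes without CTNNB1_PIK3CA replicate 2. Without PIK3CA replicate 2 they were 0.39 for enteroendocrine markers and 0.12 for p53 targets, which had 0.14 without LUC replicate 2. Stem cell, Paneth, goblet, enterocyte, replication, mitotic, FoxO, ribosome biogenesis and stress lists, each called in the same direction in both single comparisons, had an interaction of the other sign. These calls were lost with an estimated correlation. Without 1 library, those of Paneth markers in CTNNB1, of stem cell markers and stress genes in PIK3CA, and of FoxO and ribosome biogenesis genes in the interaction were lost too. The LUC libraries enter the single changes and the interaction with opposite signs, so an error in them gives this pattern too.

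The mitotic genes lay below the sum of the single changes by a median of -0.76. The highest median under the 3 scalings was -0.70 and the highest without 1 library was -0.61, without PIK3CA replicate 1, which argues against scaling or 1 library as the whole source. A less than additive effect of the transgenes stays open: with an estimated correlation the adjusted p was 0.355, and the pattern could also reflect members that vary together between libraries.

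Mptx2 (173274382 to 173277777), Mndal (173849126 to 173942491) and Mptx1 (174330518 to 174332873), all on chromosome 1, were high in both LUC libraries and PIK3CA replicate 1 and low or at 0 in the other 5; Mptx1 had 4656 normalized counts in PIK3CA replicate 1 and 94.3 in PIK3CA replicate 2. If the PIK3CA transgene lowered them, PIK3CA replicate 1 would lack its activity, but the 35 genes called in CTNNB1_PIK3CA against CTNNB1 had moved in the same direction there by a median log2 of 0.61 (SE 0.101), against 0.77 in PIK3CA replicate 2. Fewer Paneth cells in PIK3CA replicate 2 would lower the other Paneth markers, whose median difference was 0.0132 (SE 0.152, 15 members). A genome difference at this segment stays open only if it varied within the PIK3CA group. Tested genes there overlapping none of the 3 (Aim2, Ifi202b, Spta1) differed by a median of 1.39 (SE 1.33), too few and spread to decide. Aim2 (1595, 1854 and 1686 in the 3 libraries, 483 to 645 in the others) and Ifi202b (16.3, 10.1 and 14.2, and 0 in the others) split the libraries in the same way, and Spta1 did not. Mptx1 and Mptx2 are paralogs that may share reads, which was not tested.

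Pseudogenes made up 15 of the 58 genes changed at least 4-fold in PIK3CA against LUC, or 25.9%, against 5.76% of tested genes (Fisher exact p = 6.59e-07, odds ratio 5.78), 6 higher and 9 lower. Reads taken from a changed parent gene would move the parents the same way, but their median log2 change in the direction of the copy was -0.17 (SE 0.167, 13 parents). PIK3CA activity would raise the higher copies in CTNNB1_PIK3CA as well, where their median log2 change against LUC was 1.22 (SE 0.474, 6 copies) and 3.83 in PIK3CA. The 9 lower copies were lower in CTNNB1_PIK3CA too (median -2.72, and -3.33 in PIK3CA), but also in CTNNB1, which lacks the PIK3CA transgene, by a median of -3.25 (SE 0.724). A difference of the genome between the mouse lines stays open, as untested.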

How the results depend on the processing

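TMM scaling and the edgeR, DESeq2 and voom fits were added after the results were seen. Over all alternatives, 70 gene counts stayed within 1.5 times the reported ones and 49 did not, and for the number of lists called these were 72 and 12. Of single gene results, 6228 kept their direction and side of the threshold and 775 kept the direction only. Of single list results, 2121 were the same, 167 lost and 62 gained a call, and 2 reversed. TMM and edgeR left each gene count within 1.5 times. The fit of only the groups compared has no value for the interaction.

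A fold of at least 2, which takes a subset, gave 1032 genes in CTNNB1, 253 in PIK3CA and 1759 in CTNNB1_PIK3CA against LUC and 175 in CTNNB1_PIK3CA against PIK3CA. DESeq2 gave 1395 in PIK3CA against LUC, 402 and 742 in CTNNB1_PIK3CA against CTNNB1 and PIK3CA, and 78 in the interaction. A fit of only the groups compared, with fewer libraries, gave 1718, 16 and 195 in the first 3 of these. For CTNNB1_PIK3CA against CTNNB1 the count was 65 with quantile normalization, 78 with upper quartile scaling, 138 with no filter, 23 with a stricter filter and 82 with a pseudocount of 10. For the interaction it was 41 with no filter and 3 with voom. Except for the fold, the cause was not tested. Without 1 library the counts had a range of 815 to 2987 in CTNNB1, 32 to 1442 in PIK3CA and 1715 to 4589 in CTNNB1_PIK3CA against LUC, 6 to 590 and 77 to 894 in CTNNB1_PIK3CA against CTNNB1 and PIK3CA, and 1 to 64 in the interaction.

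With an estimated correlation, 0 lists were called by camera in each comparison, where unadjusted p was under 0.05 for 5, 1 and 3 lists in CTNNB1, PIK3CA and CTNNB1_PIK3CA against LUC, 0 and 5 in CTNNB1_PIK3CA against CTNNB1 and PIK3CA, and 3 in the interaction. The self-contained fry test called 0 in PIK3CA against LUC, in CTNNB1_PIK3CA against CTNNB1 and in the interaction, where unadjusted p was under 0.05 for 11, 9 and 6 lists, and 7 in CTNNB1_PIK3CA against PIK3CA. Without 1 library the number of lists called was 11 to 15, 13 to 14 and 13 to 16 in CTNNB1, PIK3CA and CTNNB1_PIK3CA against LUC, 6 to 16 and 11 to 16 in CTNNB1_PIK3CA against CTNNB1 and PIK3CA, and 9 to 12 in the interaction.

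Lists that lost their call with an estimated correlation had these adjusted p. CTNNB1 against LUC had 0.146 (stem cell), 0.161 (enterocyte), 0.248 (Wnt targets, goblet, tuft, replication, mitotic), 0.274 (enteroendocrine), 0.426 (ribosome, stress), 0.580 (Paneth, FoxO) and 0.693 (interferon). PIK3CA against LUC had 0.421 (stem cell, Paneth, goblet, enterocyte, replication, mitotic, FoxO, amino acid, unfolded protein), 0.423 (ribosome, YAP, stress, mitochondrial) and 0.484 (tuft). CTNNB1_PIK3CA against LUC had 0.334 (stem cell), 0.393 (Wnt targets, goblet, tuft, enterocyte, replication, mitotic, FoxO, amino acid, ribosome), 0.458 (Paneth, mitochondrial), 0.536 (enteroendocrine) and 0.623 (interferon). CTNNB1_PIK3CA against CTNNB1 had 0.531 (stem cell, enterocyte, FoxO, amino acid, MAPK, YAP, unfolded protein, mitochondrial), 0.584 (enteroendocrine) and 0.705 (ribosome). CTNNB1_PIK3CA against PIK3CA had 0.166 (Wnt targets, stem cell, tuft, enterocyte, replication), 0.419 (goblet), 0.464 (enteroendocrine, ribosome, interferon), 0.517 (Paneth, mitotic, duodenal) and 0.521 (amino acid). The interaction had 0.332 (stem cell, enterocyte), 0.355 (Paneth, mitotic), 0.398 (goblet), 0.493 (enteroendocrine, p53, stress), 0.512 (replication), 0.767 (FoxO) and 0.831 (ribosome). Why the calls were lost was not tested.

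Lists that lost their call with fry had these adjusted p. CTNNB1 against LUC had 0.0595 (stress), 0.108 (FoxO), 0.193 (Paneth) and 0.242 (interferon). PIK3CA against LUC had 0.0505 (stem cell, Paneth, replication, mitotic, FoxO, amino acid, unfolded protein), 0.0515 (enterocyte), 0.0836 (goblet), 0.114 (ribosome, YAP), 0.149 (tuft, stress) and 0.193 (mitochondrial). CTNNB1_PIK3CA against LUC had 0.0516 (mitochondrial), 0.0529 (enteroendocrine), 0.0584 (Paneth) and 0.168 (interferon). CTNNB1_PIK3CA against CTNNB1 had 0.138 (stem cell, amino acid, unfolded protein), 0.148 (enterocyte, FoxO, MAPK, YAP), 0.180 (mitochondrial), 0.277 (enteroendocrine) and 0.553 (ribosome). CTNNB1_PIK3CA against PIK3CA had 0.153 (enteroendocrine, ribosome, interferon), 0.168 (Paneth, mitotic, duodenal) and 0.360 (amino acid). The interaction had 0.102 (stem cell, enterocyte), 0.113 (mitotic), 0.174 (Paneth), 0.232 (goblet), 0.252 (enteroendocrine, replication, p53, stress) and 0.652 (FoxO, ribosome). Lists called by fry alone were in CTNNB1 against LUC 0.00711 (adhesion) and 0.0155 (Notch), CTNNB1_PIK3CA against LUC 0.0249 (adhesion), 0.0279 (MAPK), 0.0375 (Notch) and 0.0447 (stromal) and CTNNB1_PIK3CA against PIK3CA 0.0112 (adhesion). The tests differ in construction, since fry does not compare a list with other genes.

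Calls lost with no filter were in CTNNB1_PIK3CA against PIK3CA 0.0871 (duodenal) and the interaction 0.0608 (p53), and calls gained in PIK3CA against LUC 0.0492 (MAPK) and CTNNB1_PIK3CA against LUC 0.0293 (MAPK). Calls lost with quantile normalization were in CTNNB1_PIK3CA against CTNNB1 0.0658 (ribosome) and CTNNB1_PIK3CA against PIK3CA 0.0875 (duodenal), and calls gained in CTNNB1 against LUC 0.0497 (YAP) and CTNNB1_PIK3CA against CTNNB1 0.010 (mitotic). Calls lost with upper quartile scaling were in CTNNB1 against LUC 0.0787 (Paneth) and CTNNB1_PIK3CA against PIK3CA 0.0503 (duodenal), and calls gained in CTNNB1_PIK3CA against PIK3CA 0.0383 (unfolded protein). With TMM scaling, each of the 168 list results was the same. The cause was not tested.

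Without 1 library, 56 list results changed. For 20 that were called with all libraries the adjusted p had these ranges. CTNNB1 against LUC had 0.00721 to 0.135 (Paneth) and 0.000896 to 0.166 (interferon). PIK3CA against LUC had 0.00236 to 0.157 (stem cell), 1.18e-06 to 0.205 (tuft), 0.000955 to 0.136 (stress) and 0.000450 to 0.208 (mitochondrial). CTNNB1_PIK3CA against LUC had 1.1e-05 to 0.0932 (Paneth) and 0.000146 to 0.103 (interferon). CTNNB1_PIK3CA against CTNNB1 had 9.19e-05 to 0.0616 (stem cell), 4.71e-05 to 0.127 (enterocyte), 1.42e-07 to 0.358 (ribosome), 1.77e-05 to 0.242 (MAPK) and 9.1e-09 to 0.388 (YAP). CTNNB1_PIK3CA against PIK3CA had 8.72e-08 to 0.182 (Paneth), 1.81e-08 to 0.182 (mitotic), 0.000117 to 0.703 (amino acid) and 0.00418 to 0.523 (duodenal). The interaction had 0.000173 to 0.613 (FoxO), 1.67e-10 to 0.765 (ribosome) and 0.00605 to 0.342 (p53). For 36 that were not called the ranges reached below the threshold. CTNNB1 against LUC had 0.0328 to 0.304 (amino acid), 0.0176 to 0.129 (YAP) and 0.0459 to 0.207 (Notch). PIK3CA against LUC had 0.00165 to 0.472 (enteroendocrine) and 0.0163 to 0.546 (glycolysis). CTNNB1_PIK3CA against LUC had 0.00707 to 0.474 (MAPK), 0.0229 to 0.606 (YAP), 0.00869 to 0.299 (stress), 0.0491 to 0.474 (unfolded protein) and 9.49e-06 to 0.453 (sex-linked). CTNNB1_PIK3CA against CTNNB1 had 0.0208 to 0.771 (Wnt targets), 0.000107 to 0.409 (Paneth), 0.000732 to 0.551 (goblet), 0.0458 to 0.454 (tuft), 0.00943 to 0.866 (replication), 0.0294 to 0.286 (mitotic), 0.00239 to 0.965 (sterol), 0.00271 to 0.907 (glycolysis), 0.0187 to 0.286 (p53), 0.000585 to 0.567 (stress), 0.00841 to 0.767 (interferon) and 5.8e-09 to 0.388 (sex-linked). CTNNB1_PIK3CA against PIK3CA had 0.00671 to 0.481 (FoxO), 0.00267 to 0.968 (glycolysis), 0.0247 to 0.603 (MAPK), 0.00795 to 0.975 (YAP), 0.00993 to 0.442 (unfolded protein), 0.00118 to 0.778 (mitochondrial) and 7.03e-09 to 0.764 (sex-linked). The interaction had 0.00253 to 0.772 (Wnt targets), 0.000945 to 0.788 (tuft), 0.0109 to 0.900 (glycolysis), 0.00850 to 0.737 (YAP), 3.42e-05 to 0.935 (interferon), 0.0278 to 0.935 (mitochondrial) and 6.18e-09 to 0.825 (sex-linked). Without CTNNB1_PIK3CA replicate 1, 16 lists gained a call, 5 lost one and 2 reversed: ribosome biogenesis (adjusted p 0.358, lower) and interferon (0.019, higher) in CTNNB1_PIK3CA against CTNNB1. Without CTNNB1_PIK3CA replicate 2, 14 gained and 6 lost a call. The 4 calls of sex-linked genes arose without CTNNB1_PIK3CA replicate 1, which left the library of the female animal alone in its group. For the others the cause was not tested.

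Depth limits the low genes: with 3 or fewer reads in a group, intervals were wide, as for Sla2 in CTNNB1 (2.96 to 752).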

Other observations

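The symbol families reported here, and Snca and its neighbours, were chosen after the data were seen.

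Over 163 families of symbols with at least 10 tested genes, camera called Hist genes in CTNNB1 against LUC (24 of 57 higher and 1 lower, median log2 1.20) and in CTNNB1_PIK3CA against LUC (25 higher and 3 lower, median 0.86, or 1.31 without CTNNB1_PIK3CA replicate 2). In PIK3CA, 5 Hist genes were higher (median 0.80), and the median interaction was -1.05 with none past the limma threshold. Nup genes of the nuclear pore were higher in 13 of 20 cases in CTNNB1 (median 0.73) and in 13 in CTNNB1_PIK3CA (0.91), and Psmd genes of the proteasome in 7 of 14 in PIK3CA (0.58) and 10 in CTNNB1_PIK3CA (0.56). Cyp genes were lower in 19 of 47 cases and higher in 3 in CTNNB1 (median -0.48), lower in 9 in PIK3CA (-0.50), and lower in 25 and higher in 3 in CTNNB1_PIK3CA (-0.80). Ces genes, which encode carboxylesterases, were lower in 5 of 14 cases in CTNNB1 (-0.61) and in 9 in CTNNB1_PIK3CA (-0.82). These medians kept their signs under TMM, upper quartile and quantile scaling. Each family call was lost with an estimated correlation, with adjusted p = 0.722 in CTNNB1, 0.749 in CTNNB1_PIK3CA and 0.903 in PIK3CA against LUC for Hist.

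Snca, on chromosome 6 (60731575 to 60829855), had no read in both CTNNB1_PIK3CA libraries and between 9.65 and 27.5 normalized counts in the other 6. Its neighbours Gprin3 (3987 and 4076) and Ccser1 (918 and 1004) were expressed in CTNNB1_PIK3CA, and Mmrn1 had no read in any library. No explanation was tested.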
